A study of Homo sapiens with 12 samples.

How the data were processed

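Polyadenylated RNA was measured by sequencing in 12 neural cultures derived from human embryonic stem cells, 6 from the line H9 and 6 from the line H1. The cultures had been differentiated for 10 weeks with inhibitors of SMAD signalling and were then exposed for 6 h to 1 µM dexamethasone, a synthetic glucocorticoid, or to the DMSO vehicle, with 3 sister cultures per line and treatment. Per the labels' protocols, the libraries were pooled and sequenced on an Illumina NextSeq over more than 1 flow cell. The labels give no flow cell, date or differentiation run for a single library, so no batch could be entered in a model. Each group was taken from the labels of line and condition, and culture numbers from the labelled source of each sample.

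Each deposited file holds raw read counts per gene, in whole numbers and not normalized, for 1 library. Per the submitters' processing notes, the tools were STAR 2.5.3a and HTSeq, for which no version is named, and the builds hg38 and GRCh38.p10. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense partner cannot be told apart, and reads shared with near-identical copies can be lost or split. The files list 63925 versioned Ensembl gene IDs each and hold no row for unassigned reads. A symbol came from the gene name table for 41836 IDs and from GENCODE 29 for a further 16248, and 5841 IDs had neither a name nor a position there. Coordinates are 1-based on GRCh38 from GENCODE 29, and 33131 IDs had a count in at least 1 library.

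Total counts ranged from 14751168 in H9 vehicle culture 3 to 27505804 in H9 dexamethasone culture 3. Genes were kept by the filterByExpr function of edgeR 4.0.16, which left 17819, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood F-test on a model with 1 mean per group over all 12 libraries, which leaves 8 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were the mean of the dexamethasone effects of the lines, the effect in each line, the difference of these effects, and H9 minus H1 in the vehicle cultures. Standard errors of log2 fold changes are the fold change divided by the square root of F. Levels are TMM-scaled CPM computed from the deposited counts, as mean ± SD over the 3 cultures of a group. Most levels in the comparison of the lines are given as the mean alone, H9 vehicle culture 3 included. Because replicates are sister cultures, p-values measure the spread between sister cultures, pooled over all groups, and not between differentiations or lines. The sister cultures were also compared in pairs within each group, and no pair agreed within sampling noise.

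Before the data were examined, 35 gene lists were fixed, 23 of pathways or functions and 12 of cell type markers, of which 34 had the 3 tested members required. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Calls "adjusted over the list alone" use the members' p-values only. The genes named were also fixed by rule before the data were examined. They are the tested members of the glucocorticoid receptor target list, the 12 largest rises and falls over both lines, 5 each way in each line, 8 each way for the difference and 10 each way between lines, all with adjusted p under 0.05 and a mean CPM of at least 1. For dexamethasone the libraries of both treatments also had to be free of overlap. Clone-based names and sex-linked identity genes were passed over, and list members with the smallest p serve as examples. The largest changes in the fit without H9 vehicle culture 3 are an addition made after the data were seen, and so is any gene named outside these rules. Some genes that the rules take in are left out of the text.

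The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, library sizes without mitochondrially encoded and the 20 most abundant genes, an additional minimum log2 change of 0.5, fits of 1 line alone, an additive model, the mean line difference over both treatments, culture number as a term, and each library left out in turn. Voom with sample quality weights, robust dispersions, culture number as a term without H9 vehicle culture 3, and the line difference in the dexamethasone cultures were added after the data were seen. Computations ran in R 4.3.3 and Python 3.11.15, with figures drawn in matplotlib 3.10.9.

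The test was checked on counts simulated from the real means and library sizes with 200 genes changed, all with a mean CPM of at least 1. Each gene had the same spread in every library. The deviation of H9 vehicle culture 3 was therefore shared over all groups and not held in its own group, unlike in the real data. For the effect over both lines on 12 libraries, 43.9% of genes with a true log2 change of 0.5 were recovered, 86.6% at 1 and 100% at 2, among 17581 genes. Without H9 vehicle culture 3 these were 80.3%, 98.5% and 100% among 17876 genes. For a change in H9 alone, the test of the difference between lines recovered 0%, 29.9% and 88.1% on 12 libraries, among 17638 genes, and 31.8%, 73.1% and 97% without H9 vehicle culture 3, among 17883 genes. Unchanged genes also passed: 10 beside 154 true calls over both lines on 12 libraries, and 11 beside 186 without H9 vehicle culture 3. For the difference between lines these were 4 beside 79 and 9 beside 135.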

Results

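The series asked how neural cultures grown from human embryonic stem cells respond in RNA to a short exposure to dexamethasone, a synthetic agonist of the glucocorticoid receptor. H9 and H1 are established embryonic stem cell lines. RNA of 12 cultures was counted, 3 per group, in the groups H9 vehicle, H9 dexamethasone, H1 vehicle and H1 dexamethasone. Total counts were 14751168 to 24728048 in the H9 vehicle group, 20871163 to 27505804 in the H9 dexamethasone group, 22839733 to 25597731 in the H1 vehicle group and 23677289 to 25495510 in the H1 dexamethasone group. H9 vehicle culture 3 stood apart from its sister cultures. It had the lowest total count, 0.607% of its counts fell on mitochondrially encoded genes against 4.80% to 5.64% in the other H9 libraries and 2.91% to 3.23% in the H1 libraries, and its root mean square log2 distance to its group was 0.853 against 0.268 to 0.309 in the other 3 groups. The total counts of genes that passed each test are therefore also given without this library. Most tallies of list members are given with it only.

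**Figure D1:**
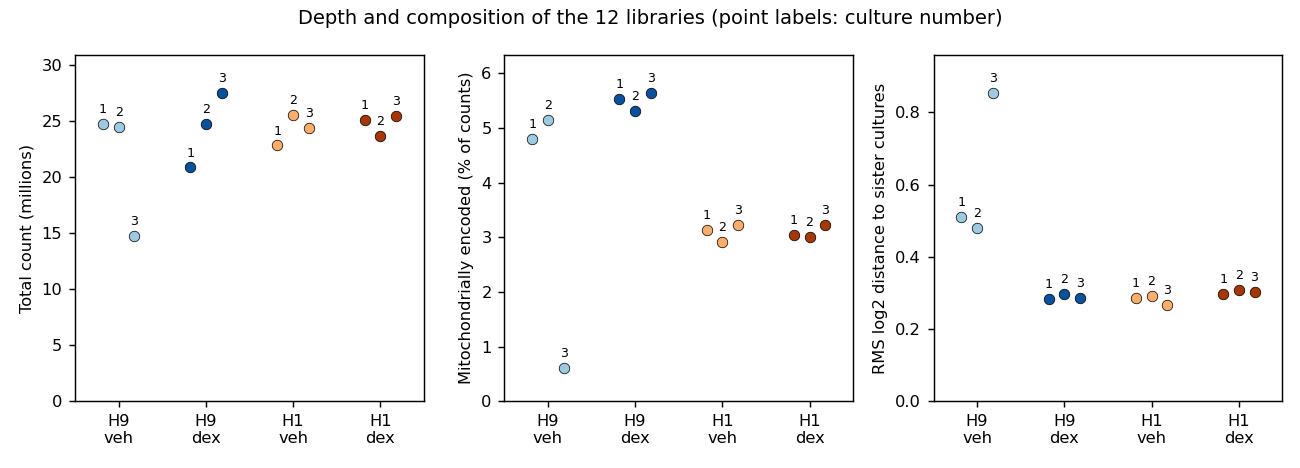
Total count, percent of counts on mitochondrially encoded genes, and root mean square log2 distance to the other cultures of the group, for each of the 12 libraries (1 point per library, labelled with its culture number; veh, vehicle; dex, dexamethasone). H9 vehicle culture 3 lies at 14751168 counts, 0.607% and 0.853.

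Dexamethasone raised a small set of genes in both lines, led by FKBP5, a co-chaperone of the glucocorticoid receptor (ENSG00000096060.14, chromosome 6, 35573585 to 35728583, minus strand). FKBP5 rose from 4.42 ± 0.57 to 28.2 ± 2.3 CPM in H9 and from 5.53 ± 0.57 to 22.3 ± 3.1 CPM in H1 (mean ± SD, n = 3 each), a log2 fold change over both lines of 2.35 ± 0.11 (SE). HIF3A, an alpha subunit of hypoxia-inducible factor (chromosome 19, 46297046 to 46343433), rose by 1.53 ± 0.12 (log2) and MT2A, a metal-binding metallothionein (chromosome 16, 56608199 to 56609497), by 1.31 ± 0.09. PER1, a repressor in the circadian clock (chromosome 17, 8140472 to 8156506), rose from 76.1 ± 16 to 151 ± 10 CPM in H9 and from 37.0 ± 0.93 to 81.5 ± 4.8 CPM in H1. The only gene that passed as lower was NR3C2, which encodes the mineralocorticoid receptor (chromosome 4, 148078762 to 148444698). It went from 15.7 ± 1.5 to 12.1 ± 0.99 CPM in H9 and from 6.96 ± 0.50 to 3.92 ± 0.32 CPM in H1. Its log2 fold change over both lines was −0.60 ± 0.09 (edgeR adjusted p = 0.0237). It passed in neither line by itself (edgeR adjusted p = 0.299 in H9 and 0.0657 in H1).

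In all, 18 of 17819 genes passed edgeR's quasi-likelihood test over both lines, 17 higher and 1 lower, and 1335 had an unadjusted p under 0.05. The 12 largest rises, each without overlap between treatments in either line, were FKBP5, HIF3A, MT2A, RASSF4 (1.30 ± 0.08), the diacylglycerol kinase DGKG (1.20 ± 0.11), TENT5B (1.15 ± 0.17), the transcription factor KLF9 (1.07 ± 0.11), PER1 (1.06 ± 0.10), the cell adhesion gene IGSF11 (1.05 ± 0.11), the Ras-related RASD1 (0.99 ± 0.14), FAM107A (0.97 ± 0.13) and the secreted protease ADAMTS9 (0.85 ± 0.07). Their adjusted p lay between 8.34e-07 for FKBP5 and 0.0214 for TENT5B. The remaining rises were TSC22D3, DDIT4 and KLF15, which belong to the receptor target list, and LIFR (0.77 ± 0.10) and PIK3R1 (0.55 ± 0.07), which are named here after their values were seen. Without H9 vehicle culture 3 the count was 140, 88 higher and 52 lower, and all 18 were among them. It was 10 without H1 vehicle culture 2 and 10 without H1 vehicle culture 3. NR3C2 passed in 3 of the 12 fits that left out 1 library, and the rises of FKBP5, HIF3A, MT2A, RASSF4, DGKG, KLF9, PER1, IGSF11 and ADAMTS9 in all 12. FAM107A passed in 10 of these fits (not without H1 vehicle culture 2 or 3), TENT5B in 6 and RASD1 in 4. With culture number as a term, 12 genes passed over both lines, all of them higher, so the fall of NR3C2 did not pass.

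**Figure D2:**
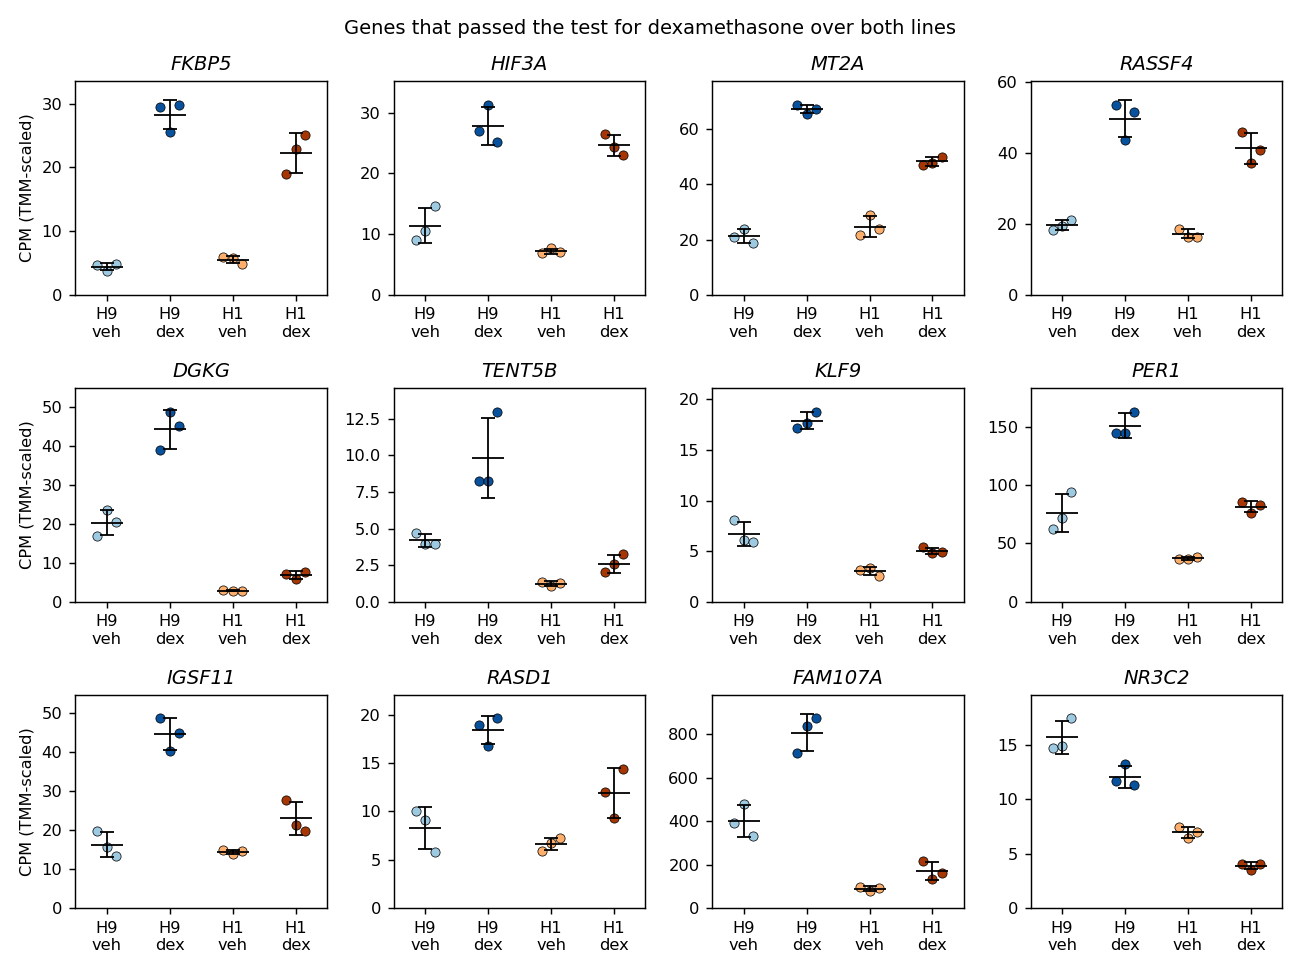
TMM-scaled CPM of 12 genes in each library (points), with the mean (bar) and SD (whiskers) of the 3 cultures per group, on linear axes that start at 0. The 11 rises lie higher in every dexamethasone library than in every vehicle library of the same line, and NR3C2 lies lower.

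Known targets of the glucocorticoid receptor rose as a group. Of 30 genes on the list fixed in advance 29 were tested, 28 had a positive log2 fold change, and the median was 0.39. The list passed camera (adjusted p = 8.59e-26, and adjusted p = 0.00279 with an estimated correlation). Over all genes tested 7 members rose, namely FKBP5, HIF3A, KLF9, PER1, KLF15 (0.67 ± 0.10), DDIT4 (0.58 ± 0.08) and TSC22D3 (0.53 ± 0.08), and 15 rose when adjusted over the list alone. KLF15, DDIT4 and TSC22D3 each passed in 2 of the 12 fits that left out 1 library. Other members well known as targets had values that did not pass, such as ZBTB16 (1.24 ± 0.22, adjusted p = 0.0916), DUSP1 (0.42 ± 0.24, adjusted p = 0.701) and SGK1 (0.16 ± 0.10, adjusted p = 0.701). Metallothioneins, which bind metal ions, also rose as a group (median 0.86, adjusted p = 1.83e-08, and adjusted p = 0.00445 with an estimated correlation). Of 10 members 4 were tested, MT2A passed over all genes, and MT2A, MT1E, MT1F and MT3 all passed when adjusted over the list alone. The metallothionein genes are near-identical in sequence, and reads shared between them make the level of a single member uncertain.

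A further 6 lists passed camera with its preset correlation, all toward higher levels, and none of them did with an estimated correlation. Markers of proliferating cells had a median log2 fold change of 0.17 with 14 of 14 members above 0 (adjusted p = 7.16e-05, and adjusted p = 0.202 with an estimated correlation), and no member passed over all genes. Genes of inhibitory neurons and GABA signalling had a median of 0.18 (adjusted p = 0.000221, and adjusted p = 0.419 with an estimated correlation). Cholesterol synthesis had a median of 0.12 (adjusted p = 0.0199, and adjusted p = 0.362 with an estimated correlation) and astrocyte markers one of 0.18 (adjusted p = 0.033, and adjusted p = 0.454 with an estimated correlation). Mitochondrially encoded messenger RNAs had a median of 0.38 (adjusted p = 0.00386, and adjusted p = 0.541 with an estimated correlation) and cytosolic ribosomal proteins one of 0.10 (adjusted p = 0.0343, and adjusted p = 0.652 with an estimated correlation). H9 vehicle culture 3, with its low mitochondrial share, moves with these last lists, whose medians without it were 0.13 (adjusted p = 4.48e-05, and adjusted p = 0.438 with an estimated correlation) and 0.00 (adjusted p = 0.745). When 1 library was left out, the astrocyte list passed in 5 of 12 fits, the ribosomal list in 6, cholesterol synthesis in 10, and the mitochondrial, proliferating cell and inhibitory neuron lists in all 12. Immediate early genes (median −0.01, adjusted p = 0.656), NF-kB and inflammatory genes (median −0.12, adjusted p = 0.552) and corticosteroid receptors and chaperones (median 0.05, adjusted p = 0.507) did not pass.

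Without H9 vehicle culture 3, a fit chosen for description after the data were seen, further genes passed over both lines. The largest additional rises without overlap between treatments were those of ZBTB16, a zinc finger transcription factor (log2 fold change 1.55, adjusted p = 7.25e-08), ANGPTL4, an inhibitor of lipoprotein lipase (1.44, adjusted p = 0.00969), and ALDH1L1, a folate enzyme used as an astrocyte marker (1.24, adjusted p = 0.000145). The largest falls without overlap included those of CLEC19A (−0.76), the cytokine IL11 (−0.75), TAFA1 (−0.75), GCNT1 (−0.66), the chemokine CCL2 (−0.58) and transforming growth factor TGFB3 (−0.49). Of the receptor target list 14 members then rose over all genes and 20 when adjusted over the list alone.

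In H9 alone, 12 genes passed as higher and none as lower, with 2898 genes at an unadjusted p under 0.05. The 5 largest rises free of overlap were FKBP5 (log2 fold change 2.68 ± 0.15), MT2A (1.66 ± 0.12), IGSF11 (1.44 ± 0.16), KLF9 (1.41 ± 0.15) and RASSF4 (1.34 ± 0.12), with adjusted p from 1.24e-05 to 0.00405, and all 5 passed in each fit that left out 1 library. With the H9 libraries fitted alone, 2 of the 12 genes passed and no others. Receptor targets rose as a list (median 0.55, adjusted p = 3.51e-15, and adjusted p = 0.0172 with an estimated correlation), with 4 members over all genes and 16 adjusted over the list alone. Without H9 vehicle culture 3, TSC22D3, ZBTB16, NFKBIA, DDIT4 and TIPARP also passed over all genes in H9. In H9 DESeq2 called 84 genes higher and 82 lower. The count was 53 (46 higher and 7 lower) without H9 vehicle culture 3, 6 without H9 dexamethasone culture 2 and 7 without H9 dexamethasone culture 3.

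In H1 alone, 9 genes passed as higher and none as lower. An unadjusted p under 0.05 was found for 526 of 17819 genes, a share below the 0.05 expected without any effect. The spread behind these p-values was pooled over all groups, H9 vehicle culture 3 included. The 5 largest rises free of overlap were ANGPTL4 (log2 fold change 2.05 ± 0.29, adjusted p = 0.0337), FKBP5 (2.01 ± 0.15, adjusted p = 0.00021), HIF3A (1.77 ± 0.16, adjusted p = 0.00109), DGKG (1.28 ± 0.17, adjusted p = 0.0169) and RASSF4 (1.27 ± 0.12, adjusted p = 0.00109). Of the 12 fits that left out 1 library, ANGPTL4 passed in 4 and DGKG in 6. Receptor targets rose as a list (median 0.26, adjusted p = 3.63e-20, and adjusted p = 0.00331 with an estimated correlation), with 4 members over all genes and 12 adjusted over the list alone. Without H9 vehicle culture 3, KLF9, TSC22D3, ZBTB16, DDIT4, KLF15 and FOXO1 also passed over all genes in H1. ANGPTL4 went from 2.02 ± 0.72 to 8.42 ± 2.1 CPM in H1 and had 0.645 ± 0.27 and 1.07 ± 0.19 CPM in the H9 vehicle and dexamethasone groups. With the H1 libraries fitted alone, 27 genes were called higher and 23 lower, the 9 among them. In that fit 1673 of 16866 genes had an unadjusted p under 0.05. In H1 DESeq2 called 20 genes higher and 12 lower, and 59 genes passed in edgeR without H9 vehicle culture 3 (30 higher and 29 lower). Leaving out an H1 library left 3 genes (without vehicle culture 1 or 3, or dexamethasone culture 1 or 3) or 5 genes (without culture 2 of either treatment). All of these fits kept H9 vehicle culture 3.

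The difference of the dexamethasone effect between lines was tested directly, and 0 genes passed in edgeR, DESeq2 or limma-voom, with 1329 at an unadjusted p under 0.05 in edgeR. On simulated counts this test recovered 29.9% of genes that changed by 1 (log2) in H9 only. Without H9 vehicle culture 3 it recovered 73.1% of such genes on simulated counts, and 0 genes passed in the real data. Of the 12 genes raised in H9 and the 9 raised in H1, 7 were shared, where independent lists of these sizes would share 0.0061 (one-sided Fisher's exact test over genes, p = 2.52e-22). Both lists came from the same fit, with a shared spread per gene, and genes are not independent, so this p-value is descriptive only. When H9 vehicle culture 3 was left out, 18 of 46 and 30 rises were shared (0.076 for independent lists), and 0 of 7 falls in H9 and 29 in H1 were (0.011 for independent lists). Across all 17819 genes the log2 fold changes of the lines had a Pearson correlation of −0.011 (Spearman −0.100). Across the 14 genes called in either line, a set chosen by these same effects, it was 0.413 (Spearman 0.235). Genes are not independent replicates, so no p-value is given for these correlations.

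**Figure D3:**
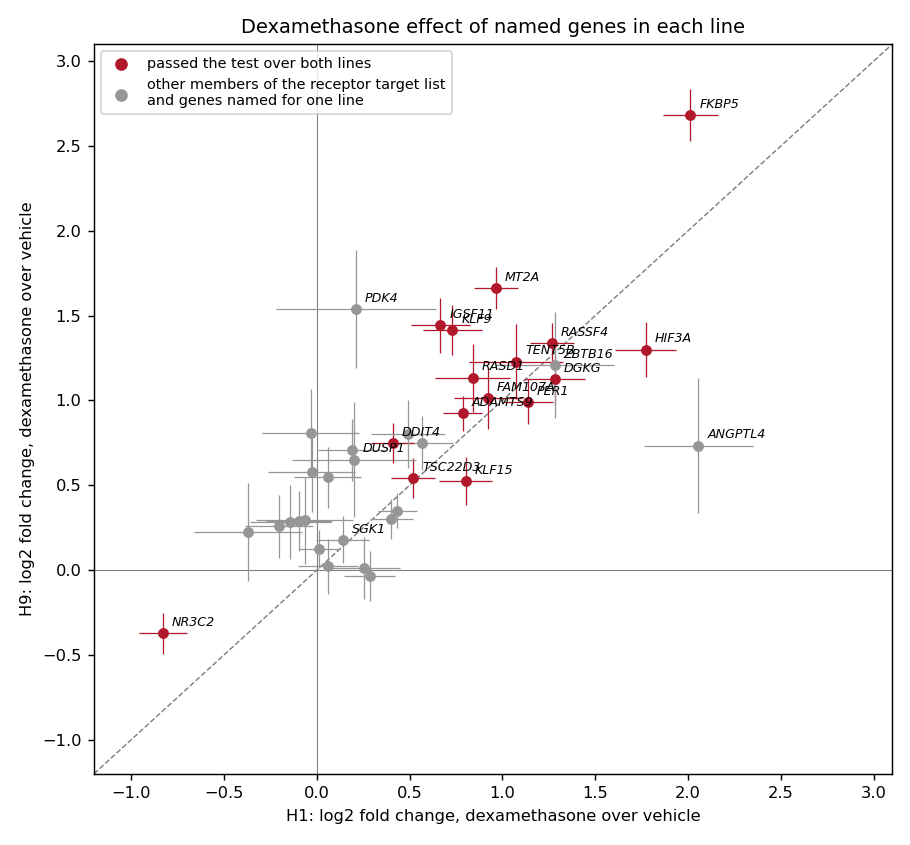
Log2 fold change of dexamethasone over vehicle in H9 (vertical axis) against H1 (horizontal axis) for the named genes and the receptor target list, with SE bars in both directions. Red points passed the test over both lines, grey points did not, and the dashed line marks equal effects. FKBP5 lies at 2.01 in H1 and 2.68 in H9.

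The vehicle cultures of the lines differed far more than the treatments did. H1 cultures held more RNA of dividing cells, with all 14 markers of proliferating cells higher than in H9 (median log2 H9 minus H1 −2.62, camera adjusted p = 2.61e-12, and adjusted p = 0.0296 with an estimated correlation). AURKB, a mitotic kinase, was at 0.985 CPM in H9 and 14.6 CPM in H1, the cyclin CCNA2 at 4.97 and 35.8, and the spindle checkpoint kinase BUB1B at 3.97 and 25.1 CPM. Immediate early genes, which neuronal activity and other stimuli induce, were higher in H9 for 20 of 22 members and lower for 2 (median 1.58, adjusted p = 5.08e-09, and adjusted p = 0.0336 with an estimated correlation). Among them NPAS4 was at 42.1 CPM in H9 and 5.59 in H1, FOSB at 22.6 and 3.93, and FOSL2 at 286 and 73.1 CPM. Without H9 vehicle culture 3 both lists kept camera's preset call but not that with an estimated correlation (adjusted p = 0.193 for each). Circadian clock genes were higher in H9 for 15 of 19 members and lower for none (adjusted p = 0.000152, and adjusted p = 0.0296 with an estimated correlation), among them BHLHE41 (2.52 ± 0.15), PER3 (0.93 ± 0.11) and DBP (1.90 ± 0.23).

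Further lists passed camera between lines with the preset correlation only. Genes of presynaptic release were higher in H9 for 18 of 21 members (median 0.79, adjusted p = 4.21e-06, and adjusted p = 0.0916 with an estimated correlation), with SYN2 at 30.1 CPM in H9 and 5.11 in H1. Neurotrophins and their receptors were higher in H9 for 11 of 14 and lower for 2 (adjusted p = 0.000464, and adjusted p = 0.0973 with an estimated correlation), including GFRA2 (2.56 ± 0.16), BDNF (1.76 ± 0.17) and the neuropeptide precursor VGF (2.47 ± 0.25). Excitatory synapse genes were higher for 15 of 22 and lower for 3 (adjusted p = 0.000464, and adjusted p = 0.322 with an estimated correlation), with the NMDA receptor subunit GRIN2A at 101 CPM in H9 and 14.4 in H1. Cholesterol synthesis was lower in H9 for 14 of 21 (median −0.70, adjusted p = 9.45e-05, and adjusted p = 0.0582 with an estimated correlation). Forebrain identity genes were lower in H9 for 8 of 18 (adjusted p = 0.000955, and adjusted p = 0.0916 with an estimated correlation), with LHX2 at 28.5 CPM in H9 and 81.6 in H1. Mesenchymal and fibroblast markers were lower in H9 for 8 of 12 and higher for 1, TWIST1 (adjusted p = 0.00298, and adjusted p = 0.297 with an estimated correlation). The collagen COL1A1 was at 32.1 CPM in H9 and 1410 in H1, and POSTN at 4.23 and 280 CPM. Astrocyte markers did not pass camera as a list (adjusted p = 0.0953), with 6 of 12 members higher in H9, 1 lower and the others not past the test. Among the 6, SPARCL1 (2.00 ± 0.13), AGT (3.06 ± 0.21) and ALDH1L1 (4.15 ± 0.31) are examples.

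**Figure D4:**
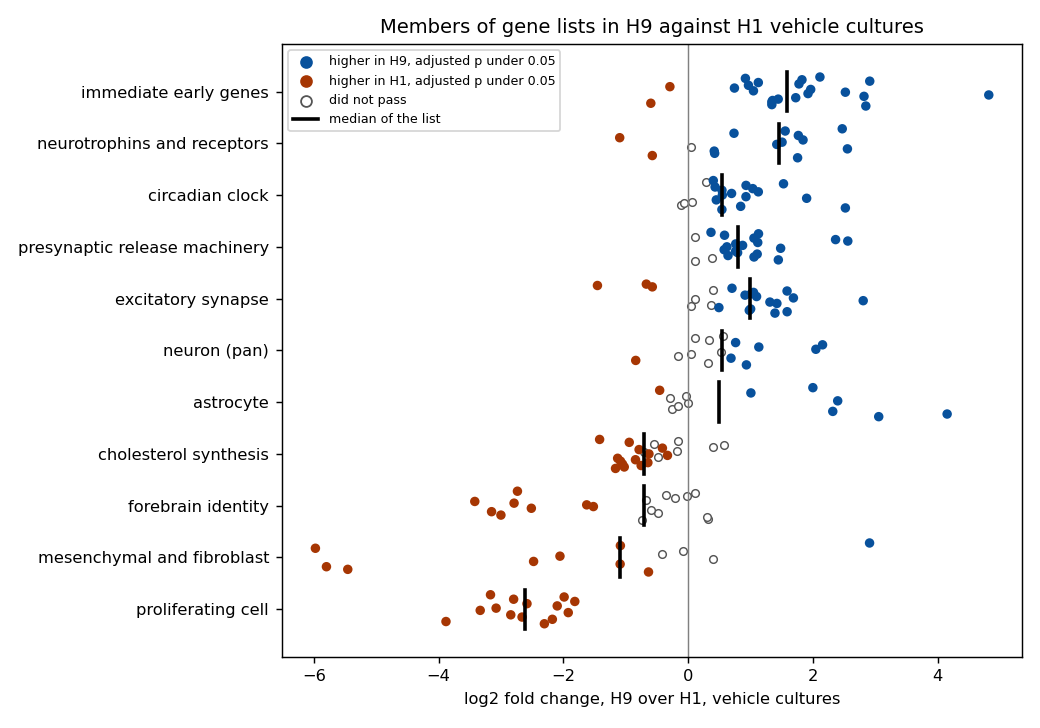
Log2 fold change of H9 over H1 vehicle cultures (horizontal axis) for each tested member (point) of 11 gene lists (rows), filled where the adjusted p was under 0.05 and open where not, with the median of the list as a black bar. All 14 markers of proliferating cells lie below 0, and 20 of 22 immediate early genes lie above 0.

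Over all genes, 8350 of 17819 passed between the lines, 4571 higher in H9 and 3779 higher in H1, and 10608 passed without H9 vehicle culture 3. The labels do not say whether the lines were differentiated together, so line and differentiation run cannot be told apart. Among the largest differences, ZNF667, a zinc finger gene (chromosome 19, 56439325 to 56478065), was at 33.7 CPM in H1 and had no count in the H9 vehicle libraries, which makes it at least 711-fold lower in H9 against a floor of 3 counts over the group. Its overlapping antisense gene ZNF667-AS1 and its neighbour ZNF471 (56507843 to 56530221) were also near absent in H9, at 0.041 and 0.0859 CPM against 40.0 and 37.6 in H1. MEG3, a long noncoding RNA of an imprinted locus (chromosome 14, 100779410 to 100861031), was at 0.399 CPM in H9 and 375 in H1. CEBPZOS, ZNF528-AS1, MIR4458HG, SPC25, LCN9 and the pseudogene PSPHP1 completed the 10 genes highest in H1 relative to H9. Higher in H9 were CBLN2, a synapse organiser, at 14.2 against 0.0657 CPM, the NMDA receptor subunit GRIN3A at 14.6 against 0.151, and the orphan receptor GPR50 at 258 against 3.19 CPM, together with ZNF558, LINC02693 (no count in the H1 vehicle libraries, at least 118-fold higher in H9) and the pseudogenes LSP1P4 and HSD17B7P2. Pseudogenes share reads with their parent genes, so their levels are uncertain. DDAH2 (5.50 ± 1.9 CPM in H9) and PPP1R11 (2.33 ± 1.8 CPM in H9, 0.272 in vehicle culture 3) had no count in the H1 vehicle libraries. They were at least 144-fold and 65.7-fold higher in H9. Both lie on chromosome 6 between 29 and 33 Mb, where 6.58% of protein-coding genes could be tested against 59.2% in the 6 Mb on each side. The floors cover counting error only.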

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

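The thinning test and the counts of other splits were planned before their results were seen, and the other tests of explanations in this part were chosen after. A pair of them was also revised after a first result: the slope below replaced a mean of positions that had left the question open, and the comparison of the deviation left after GC content and length was added because 25.3% lay between the bounds first set. A comparison of large folds in the histocompatibility region with its sides was dropped, since it counted the genes that had drawn attention to the region. No gene passed edgeR's test of a difference between lines in the response to dexamethasone over the 12 libraries (1329 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0), but a pair of gene lists passed camera with the preset correlation. Mitochondrially encoded messenger RNAs had a median difference of the effect (H9 minus H1) of 0.68 on the log2 scale (adjusted p = 0.0259, 12 of 13 members above 0), and cytosolic ribosomal proteins one of 0.321 (adjusted p = 0.0115, 21 of 24 members above 0). Both were lost with an estimated correlation (adjusted p = 0.841 each). Without H9 vehicle culture 3 the medians were 0.13 (adjusted p = 0.00878, and adjusted p = 0.939 with an estimated correlation) and 0.11 (adjusted p = 0.0532), and receptor targets passed with a median of 0.16 (adjusted p = 0.0146, and adjusted p = 0.805 with an estimated correlation).

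H9 vehicle culture 3 stood apart from its sister cultures, with 2104 genes over 2-fold higher and 2150 over 2-fold lower than the mean of the other H9 libraries, where the other H9 libraries had 146 to 215 such genes in all. Its lower depth was not enough for this, since the sister cultures thinned to its total lay 0.372 apart, 43.9% of its distance of 0.846 to them. GC content and transcript length took up 25.3% of the variance of its deviation over genes and left a root mean square of 0.761, against at most 0.330 in any other library, which argues against them as the whole cause. It was not a dexamethasone culture under the wrong label by the genes raised in H1, where its slope from the vehicle (0) to the dexamethasone level (1) was 0.153 ± 0.091 (SE, 9 genes; a mean of per-gene positions gave 0.344 ± 0.16), nor an H1 culture, with a mean position of 0.104 between H9 (0) and H1 (1) over 3591 genes. A difference in RNA handling or in the culture itself stays open, and no biological explanation was tested.

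Genes of the major histocompatibility complex region on chromosome 6 differed by large folds between lines. Of 152 protein-coding genes between 29 and 33 Mb 10 could be tested (6.58%), against 116 of 196 in the 6 Mb on each side (59.2%, two-sided Fisher's exact test over genes, p = 1.26e-26). Of the 10 tested, 6 had an absolute log2 line difference above 4, and 5 of the 6 kept one above 4 in the dexamethasone cultures, which argues against the H9 vehicle library that stands apart. The low share of genes tested is consistent with reads lost to near-identical alternate sequences of the region in the reference, but whether such a loss gives rise to the line differences was not tested. A biological difference in these genes between lines stays open and untested.

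The lists of proliferating and mesenchymal cell markers passed camera toward lower levels in the H9 than in the H1 vehicle cultures with the preset correlation, the latter with 8 of 12 members lower and 1 higher. With an estimated correlation the mesenchymal list did not pass (adjusted p = 0.297), and the proliferating list passed over 12 libraries (adjusted p = 0.0296) but not without H9 vehicle culture 3 (adjusted p = 0.193). In the dexamethasone cultures the median of the proliferating cell markers was −2.334, against −2.62 in the vehicle cultures, and that of the mesenchymal markers was −1.19 against −1.09, which argues against H9 vehicle culture 3 as the source of either. A lower share of neurons in H1 would raise the markers of every other cell type there only if those types kept their proportions to each other. Of 6 lists of other cell types, 2, astrocytes and choroid plexus, were higher in H9 by fry without that library (adjusted p = 9.35e-05 and 0.000347), while 2 were lower. In that fit 10608 of 18098 genes passed between lines, so fry calls in either direction were likely for any list. These lists therefore do not decide whether H1 held a lower share of neurons. A change in the proliferating or mesenchymal cells themselves may be the source, but line and differentiation run cannot be told apart in this design.

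The count of 18 genes over both lines was reached by no other of 100 splits of the treatment labels within lines (1 of 100, highest other 0). The same held for the count of 140 without H9 vehicle culture 3 (1 of 100, highest other 5). A wrong split moves part of the treatment effect into the spread between cultures, which lowers its count. These splits of sister cultures therefore bear on the number of genes and not on each gene. For the glucocorticoid receptor target list, the unadjusted camera p of 2.53e-27 was the smallest in 100 splits (1 of 100, smallest other 1.93e-14). Chance cannot be excluded for the number of lists past the threshold, since 16 of the 100 splits gave at least 8 lists and the highest other gave 13. Nor can it be for the correlation of −0.011 between lines, which 59 of 100 reached (highest other 0.17). For the difference between lines all 100 splits gave at least the real count of 0. No count can lie below 0, so this outcome was fixed in advance and decides nothing. The highest was 18, which is the effect over both lines with the labels of 1 line exchanged. For each line alone and for the line difference the 10 possible splits are too few for a share under 0.05, with real values of 12, 9 and 8350 (each 1 of 10) and a highest other of 0 in all 3.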

How the results depend on the processing

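Voom with sample quality weights, robust dispersions, the replicate block without H9 vehicle culture 3 and the line difference in the dexamethasone cultures were chosen after seeing the data. Over both lines, 18 genes became 116 with DESeq2 (79 higher, 37 lower), 30 with no filter, 212 with quality weights (123 higher, 89 lower) and 10 to 140 when 1 library was left out. In H9, 12 became 166 with DESeq2, 24 with no filter, 263 with quality weights, 2 with the H9 libraries fitted alone and 6 to 53 with 1 library left out. In H1, 9 became 32 with DESeq2, 110 with quality weights, 50 with the H1 libraries fitted alone and 3 to 59 with 1 library left out. Among the fits that left out 1 library, the one without H9 vehicle culture 3 gave the highest value in each case and lowered the common biological coefficient of variation from 0.164 to 0.0729, and its quality weight was 0.042. The cause of the other changes was not tested. The difference between lines stayed at 0 genes in every alternative except the replicate block without H9 vehicle culture 3. The line difference of 8350 genes ranged from 6711 to 10608 with 1 library left out and fell to 3881 with culture number as a replicate block across lines on the 6 vehicle libraries, a fit of fewer samples. The correlation of −0.011 between lines was 0.413 over genes called in either line, and ran from −0.05 to 0.081 with 1 library left out, positive without H9 vehicle culture 3 (0.081), H1 dexamethasone culture 1 (0.059), H1 vehicle culture 2 (0.017) and H9 dexamethasone culture 2 (0.003), and 0 without H1 vehicle culture 3; the cause was not tested. Of 8 lists past the threshold, 2 held with an estimated correlation and 2 with fry. The labels do not say that culture numbers pair the samples, and the data leave it open: same-numbered cultures of a line had correlations of 0.021, 0.294 and 0.17 in H9 and 0.448, 0.167 and 0.069 in H1, all above 0 but not all above 0.1, against −0.458 to 0.233 for different numbers, and not every culture correlated best with its own number. The replicate block within lines gave 12 genes over both lines, 8 in H9, 6 in H1 and 0 for the difference; without H9 vehicle culture 3 it gave 235, 93, 297 and 2, the last being SIM2 (−1.45, adjusted p = 0.00174) and CPAMD8 (1.54, adjusted p = 0.00372), at adjusted p = 0.548 each over 12 libraries and 0.31 and 0.306 without that culture and no block, and the cause was not tested. No list or named gene past the threshold changed sign in any alternative, while 27 of the 2156 values of lists and named genes under alternatives changed sign with neither fit past the threshold. For genes with 0 counts in a line, depth allows only a bound on the fold.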

Other observations

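The tests in this part were chosen after the results were seen, and both were read as undecided only after the small number of genes was known. Single genes of the fixed lists, chosen after their values were seen, differed between the lines in both directions. TPH2, the rate-limiting enzyme of serotonin synthesis in neurons, was at 10.6 CPM in the H9 and 0.323 CPM in the H1 vehicle cultures, and FEV, a transcription factor of serotonergic neurons, at 2.70 and 0.053 CPM. The midbrain and hindbrain factors LMX1A (10.5 and 1.01 CPM) and LMX1B (7.57 and 1.16 CPM) and the homeobox gene HOXC4 (20.9 and 2.49 CPM) were also higher in H9. Lower in H9 were the transcription factors TBR1 at 3.72 CPM in H9 and 25.2 in H1, NEUROD6 at 0.850 and 9.29, and EOMES at 1.22 and 10.6, as well as DLX1 (21.8 and 69.4) and DLX2 (log2 H9 minus H1 −1.99 ± 0.30). The list of monoaminergic and cholinergic neurons was higher in H9 for 7 of 11 members and lower for 1 (camera adjusted p = 0.00941, and adjusted p = 0.0916 with an estimated correlation), while hindbrain and spinal cord identity, with 3 of 10 tested members higher in H9, did not pass (adjusted p = 0.0972). That list has 22 members, and several untested ones, such as HOXA5, HOXB4 and HOXC6, had 0 counts over the 12 libraries. The reason was not tested, so neither this list nor HOXC4 alone settles regional identity.

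Of 12 microglial markers 1 reached the filter, and of 10 markers of pluripotent stem cells 3 did. These numbers alone do not show absence, since AIF1 and POU5F1 lie in the histocompatibility region, where few genes could be tested, and genes of other lists also had 0 counts over the 12 libraries (SOX2, HES5, ASNS and CYP51A1). The other untested markers had few counts over the 12 libraries, at most 44 for microglia (CSF1R) and 10 for stem cells (PRDM14). Of the 3 pluripotency markers tested, DPPA4 was at 3.97 CPM in H9 and 0.145 in H1. A single marker does not show that stem cells remained.

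Some genes were counted in every library of one line and in almost none of the other. With at least 1 CPM in all 6 libraries of a line and at most 3 counts over the 6 of the other, and with sex-linked identity genes and the histocompatibility region with 1 Mb on each side left out, there were 9 such genes in H1 and 5 in H9. A hypothesis was that zinc finger genes are over-represented among them. Of the 6 that code for protein, 1 was a zinc finger gene (ZNF667), 16.7% against 3.18% of the other tested protein-coding genes (one-sided Fisher's exact test, p = 0.176), too few to tell. A second hypothesis was that such genes lie next to one another, as genes silenced together might. Within 100 kb of another from the same line lay 2 of the 14, ZNF667 and ZNF667-AS1, a number that 106 of 10000 random sets reached. They overlap, and with the antisense gene left out the number was 0. ZNF471, which overlaps neither and starts within 100 kb of both, exceeded the limit of 3 counts but was also near absent in H9 (0.0859 CPM against 37.6 CPM in the H1 vehicle cultures), so reads shared between the overlapping pair do not account for all of the neighbourhood. AL117190.2, another of the genes counted in H1 (chromosome 14, 100834432 to 100861026), lies within the bounds of MEG3. MEG3 also exceeded the limit but was near absent in H9 (0.399 CPM against 375 CPM in the H1 vehicle cultures). ZNF471 and MEG3 were brought in after their values were seen. Such neighbourhoods are too few to tell whether these genes lie together more often than others.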
